A study of Mus musculus with 5 samples.

How the data were processed

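The data are droplet single-cell RNA-seq of mouse cortical neurons labelled with CTB 555 from the cerebral peduncle (SCPN, 2 samples at P1 and 2 at P3) or from spinal level C2 (CSN, 1 sample at P3). Per the labels' protocols, cortex with labelled cells was dissected, dissociated and sorted in 2 rounds, and libraries were made with a Chromium 3' kit of version 3.1. The authors deposited raw UMI counts per gene and cell, as whole numbers, per the file headers, for 11 runs of the 5 samples, with 31053 genes. The submitters' processing notes name Cell Ranger 6.0.1 and the genome build mm10. The file folders mark the matrices as filtered, so that barcodes without cells had been removed before deposit. An annotation of cell types was not used here, and classes were rebuilt from the counts. Counting with or without strand is not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies such as Hba-a1, are uncertain. Groups come from the sample titles, and description codes 2012 and 2106 in the labels coincide with replicate numbers 1 and 2 of the SCPN samples and 2106 with CSN.

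The runs of a sample were summed, after a check that no pair of runs shared more than 11 barcodes. Cells with at least 1000 genes and at most 10% mitochondrial UMIs were kept: 3522 of 6614 and 4674 of 7862 barcodes at P1, 3201 of 4864 and 9840 of 14747 at P3, and 2616 of 5136 in CSN, or 60.8% in all. Kept cells had medians of 6108, 4359.5, 7288, 4215 and 6784 UMIs. The mitochondrial limit alone removed 2241, 1618, 608, 2751 and 1710 barcodes, so it weighs on shares. Scrublet, run per run with an expected rate of 6%, called 32 of 39223 barcodes as doublets (0.0816%). At so low a share the caller is taken not to have worked. Whether doublets were removed before deposit is not given in the sources used here and was not tested. An alternative removed the highest 5% of its scores in each run. Counts were scaled to 10000 UMIs per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering at a resolution of 1 with no integration (scanpy 1.11.5, leidenalg 0.10.2, random seed 0).

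Clusters were named from 18 marker lists written before the data were examined, as were the 14 gene lists, the tests, the rule for named genes and a first set of alternatives. A cluster took the name of the best-scoring list if at least 3 of its markers were detected (in at least 10% of cells), unless its 10 leading genes held more markers of another class. The number of markers and a further guard were set after seeing the data: cluster 21, led by Mgat4c, Grp, Tshz2 and Etv1, was left unnamed as it carries genes of near-projecting neurons. It held 1.36 and 1.09% of cells at P1, 2.22 and 3.08% at P3 and 0.306% in CSN. Unnamed clusters held 10.5% ± 0.236 of cells at P1, 11.5% ± 3.31 at P3 and 17.8% in CSN, among them cycling cells with microglial genes. Immune genes led microglia-like clusters 17 (H2-Eb1, Cd74, Iigp1 and Gbp2) and 27 (Cd52 and Gbp2). The remaining classes named, with their shares at P1, at P3 and in CSN, were corticothalamic-like (2.31, 3.75 and 1.38%), oligodendrocyte-like (1.55, 4.10 and 0.612%), striatal-like (1.50, 1.35 and 0.153%), border macrophage-like (0.0428, 1.71 and 1.99%), mural-like (0.206, 0.520 and 0.726%) and choroid-like cells (1.67, 0.830 and 0.573%). No cluster was named after the subplate, Cajal-Retzius, progenitor, fibroblast or erythroid lists.

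For the tests, raw counts of SCPN-like cells were summed per sample (7282607 and 10622153 UMIs at P1, 12088372 and 18140776 at P3, 7512331 in CSN, from 1079, 2550, 1153, 4632 and 1291 cells). edgeR 4.0.16 (R 4.3.3) fitted the 3 groups together with its quasi-likelihood test, TMM scaling and its own filter on low counts, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CSN has no replicate, so its spread is that of the SCPN samples. The correlation over genes was 0.965 between the P1 replicates and 0.970 between the P3 replicates, and no samples were duplicates. For the Npy and Crim1 splits, each cell was thinned to 2000 UMIs, the 10th percentile in the shallowest sample rounded down to a whole 1000. Cells with at least 1 UMI of the gene and the others were summed per SCPN sample, and the sample was a block. CPM values given as raw are UMIs divided by the total of the summed cells, without TMM factors. The gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, beside an estimated correlation and fry, with Benjamini-Hochberg over the lists of a kind. DESeq2 1.42.0 was an alternative, and its missing adjusted p-values were left out of counts.

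Named genes are the 12 with the largest and the 12 with the most negative change among those that passed with a mean log2 CPM of at least 4 and the same sign in each code or sample, leaving out predicted, ribosomal and mitochondrial genes. To these come up to 4 members of each list with the smallest p and a fixed set that includes Npy, Crim1, Klhl14, Crym and Fezf2. Some genes that the rule selects are not reported here. If none passed, the 5 with the smallest p in each direction are given. Gad1 and Gad2 fell under the count filter in each test, and Sst in the splits. Cluster and pattern genes in the closing section were chosen after their values were seen. Positions of all 151 named genes come from GENCODE vM21 on mm10, matched by Ensembl identifier.

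Tests were checked on simulated data made from these samples with changed genes at log2 folds of 1 and 2. edgeR recovered 54 and 99% of them for P1 against P3 (14150 genes), 25 and 95% for CSN against SCPN (14263 genes), 88.9 and 100% for the Npy split (9544 genes), and 99 and 100% for the Crim1 split (10284 genes). DESeq2 recovered 48 and 95% for P1 against P3 and 13 and 93% for CSN against SCPN. Of edgeR's calls on the simulated data, 7.27, 3.23, 6.03 and 6.13% were false in these 4 comparisons, and of DESeq2's 4.03 and 7.83%, at a threshold of 5%. The simulation gave all genes of a comparison the same spread and changed only genes above a minimum mean count. It did not hold the unlike cluster mixtures of the real samples, so real recovery may be lower. For CSN against SCPN, Npy (log2 difference -5.30) and Stxbp6 (-3.48) did not pass in the real data. Shares carry exact binomial 95% intervals.

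Alternatives fixed before the data were examined were other size factors, DESeq2, no count filter, the description code as a replicate block, all excitatory or all kept cells, called doublets kept, thinning or its absence, at least 2 UMIs per positive cell, cells with Gad1, Gad2 or Slc32a1 left out, a resolution of 2, at most 5% mitochondrial UMIs, at least 500 genes, and each sample left out in turn. Chosen after seeing the data were the removal of the highest 5% of doublet scores, a mitochondrial limit of 20%, the removal of cluster 25, shares and lists without each sample, and the alternatives of the tests of age in the splits and in callosal-like cells. Python steps used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.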

Results

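Mouse cortical neurons were labelled from their axons with the tracer CTB 555, a fluorescent form of the cholera toxin B subunit, purified in 2 rounds of fluorescence sorting and profiled by droplet single-cell RNA-seq. SCPN, which the field uses for subcerebral projection neurons, were labelled from the cerebral peduncle and collected at postnatal day 1 (P1) or 3 (P3). CSN, corticospinal neurons, were labelled from spinal level C2 and collected at P3. There were 2 SCPN samples at P1, 2 at P3 and 1 CSN sample. The title places the work in the development of a cortico-brainstem circuit for skilled forelimb movement. The comparisons asked which genes differ with age, with the site of labelling, and between neurons that do or do not express Npy or Crim1. The 5 samples held 43253048 and 38309624 UMIs (unique transcript molecules) at P1, 35048160 and 80424144 at P3, and 38277544 in CSN, in replicate order. The files held 39223 barcodes, of which 23853 passed the filters on cells. The labels do not say that the replicates came from separate animals. The p-values for age and site of labelling thus measure the spread between these samples, which may be technical. For neurons with and without Npy or Crim1, the sample was a block, so differences between samples were taken out. Those p-values concern only how the difference between the positive and negative sums varied from sample to sample. In all fits edgeR pools part of the spread over genes. A gene's p-value and SE can thus be smaller than its own samples alone would give.

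Deep-layer neurons with subcerebral markers were the largest named class in each sample. Excitatory clusters that scored best for a list of subcerebral genes such as Bcl11b, Fezf2, Ldb2, Crym and Crim1 were called SCPN-like. They made up 30.6% (29.1 to 32.2) and 54.6% (53.1 to 56.0) of kept cells in the P1 samples, 36.0% (34.4 to 37.7) and 47.1% (46.1 to 48.1) in the P3 samples and 49.4% (47.4 to 51.3) in CSN. Ranges are exact binomial 95% intervals, which cover counting error only. The group means were 42.6% ± 16.9 at P1 and 41.5% ± 7.82 at P3 (SD, n = 2 each), so the replicates differed by more than the means. Both sorting rounds and the filters can set these shares. The name was given relative to other excitatory clusters and was weak for some. The mean log2 score of the list ran from 0.073 in cluster 2 and 0.147 in cluster 12 to 0.812 in cluster 13. Clusters 2, 3, 5, 9 and 12 had none of its markers among their 10 leading genes. The sorted cells also held other classes. Callosal-like neurons made up 14.2% ± 4.15, 9.11% ± 8.28 and 4.85% of cells at P1, at P3 and in CSN. Microglia-like cells made up 11.99% ± 2.95, 11.6% ± 7.51 and 13.5%, and astrocyte-like cells 8.15% ± 2.78, 8.56% ± 5.17 and 3.44%. GABAergic-like cells were at 4.54% ± 3.90, 3.06% ± 2.44 and 0.879%, and endothelial-like cells at 0.704% ± 0.330, 2.39% ± 0.337 and 4.78%. With 2, 2 and 1 samples no exact test of a share can pass a threshold of 0.05, and none was run.

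Different clusters held most of the SCPN-like class in each sample, so the values within it compare unlike mixtures. In P1 replicate 1 these were cluster 0 (28.5%, led by Brinp3 and Cntn6) and cluster 12 (22.8%, led by Npy, Klhl14 and Sema3e). In P1 replicate 2 they were cluster 0 (30.0%), cluster 2 (21.5%, Cbln2) and cluster 9 (15.8%, Sorcs3). In P3 replicate 1 they were cluster 3 (35.8%, Cartpt, Thy1, Snhg11 and Lynx1), cluster 5 (21.2%, St6galnac5) and cluster 9 (13.1%). In P3 replicate 2 they were cluster 4 (26.1%, Rxfp1), cluster 2 (16.7%), cluster 13 (13.9%, Vgf) and cluster 3 (13.8%). In CSN they were cluster 0 (40.7%), cluster 3 (24.7%) and cluster 5 (23.5%). A further cluster, 25, was led by S100a10, Nrgn and Gap43 and stood apart in ribosomal protein UMIs, with 9.65% against at most 3.36% in the other SCPN-like clusters. It held 7.88 and 5.96% of SCPN-like cells at P1, 3.21 and 0.777% at P3 and 3.18% in CSN.

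Npy, which encodes neuropeptide Y (ENSMUSG00000029819, chromosome 6, positions 49822710 to 49829507, plus strand), was detected in a minority of SCPN-like cells in the SCPN samples and at background in CSN. After each cell was thinned to 2000 UMIs, 22.4% (19.9 to 25.04) and 10.9% (9.65 to 12.2) of SCPN-like cells at P1 had an Npy UMI. The shares were 10.6% (8.91 to 12.6) and 6.65% (5.92 to 7.44) at P3, and 0.49% (0.181 to 1.07; 6 of 1216 cells) in CSN. The group means were 16.6% ± 8.13 at P1 and 8.64% ± 2.83 at P3 (SD, n = 2 each), and the P1 replicates lay further apart than the means of the ages. Microglia-like cells, which should lack Npy, gave 0.806 and 0.433% at P1, up to 0.845% at P3 and 0.567% in CSN. Astrocyte-like cells gave more, 1.07 to 2.38%, and oligodendrocyte-like cells 3.13 to 6.67%, the highest from 1 of 15 cells in CSN. The CSN share lay at the microglia-like background, while the 4 SCPN shares lay above these 3 classes of the same sample. In P3 replicate 2 the interval of the oligodendrocyte-like share (0.649 to 8.86) reached past the SCPN-like share. Other neurons had Npy too. Corticothalamic-like shares were 25.7 and 11.8% at P1, 20.7 and 12.2% at P3 and 19.2% in CSN, above SCPN-like cells in each sample. GABAergic-like shares were 5.11 and 7.14% at P1, 8.87 and 11.1% at P3 and 23.5% in CSN. Callosal-like shares were 12.8 and 4.44% at P1, 26.5 and 19.2% at P3 and 12.2% in CSN. Few cells lay behind some, 17 corticothalamic-like in P1 replicate 2 and 17 GABAergic-like in CSN. Without thinning the SCPN-like shares were 25.6, 12.7, 16.7, 7.91 and 1.07%. Median depth before thinning was 5362, 3608.5, 9951, 3422 and 5270 UMIs in SCPN-like cells and 14581, 13286.5, 16503, 7864 and 12316 UMIs in microglia-like cells, in the order P1, P3, CSN. Thinning left out 34, 227, 16, 359 and 75 SCPN-like cells. In raw sums over SCPN-like cells, Npy stood at 585 and 292 CPM (UMIs scaled to the sample's total) at P1, 151 and 111 CPM at P3 and 3.33 CPM in CSN.

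Crim1, a transmembrane protein gene used as a marker of corticospinal neurons (ENSMUSG00000024074, chromosome 17, positions 78200248 to 78376592, plus strand), was detected most often in CSN. The thinned shares were 24.8% (22.2 to 27.5) and 28.1% (26.3 to 30.0) at P1, 33.2% (30.5 to 36.1) and 29.5% (28.1 to 30.9) at P3, and 39.9% (37.1 to 42.7) in CSN, with 3.63 to 5.10% in microglia-like cells. Group means were 26.4% ± 2.35 at P1 and 31.4% ± 2.67 at P3 (SD, n = 2 each), and unthinned shares were 50.2, 45.9, 70.4, 44.0 and 64.7%. Other classes reached higher thinned Crim1 shares than microglia-like cells, up to 11.3% in astrocyte-like and 10% in endothelial-like cells. Other neurons reached 11.4% in callosal-like and 17.8% in GABAergic-like cells. Corticothalamic-like shares were 29.4% in P1 replicate 2 (5 of 17 cells) and 34.1% in P3 replicate 2, above SCPN-like cells of the same sample. The intervals of both reached below the SCPN-like share. In the remaining samples corticothalamic-like shares lay below those of SCPN-like cells. Crim1 was also 1 of the markers that named the SCPN-like clusters, so the SCPN-like shares are within cells chosen partly by it.

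**Figure D1:**
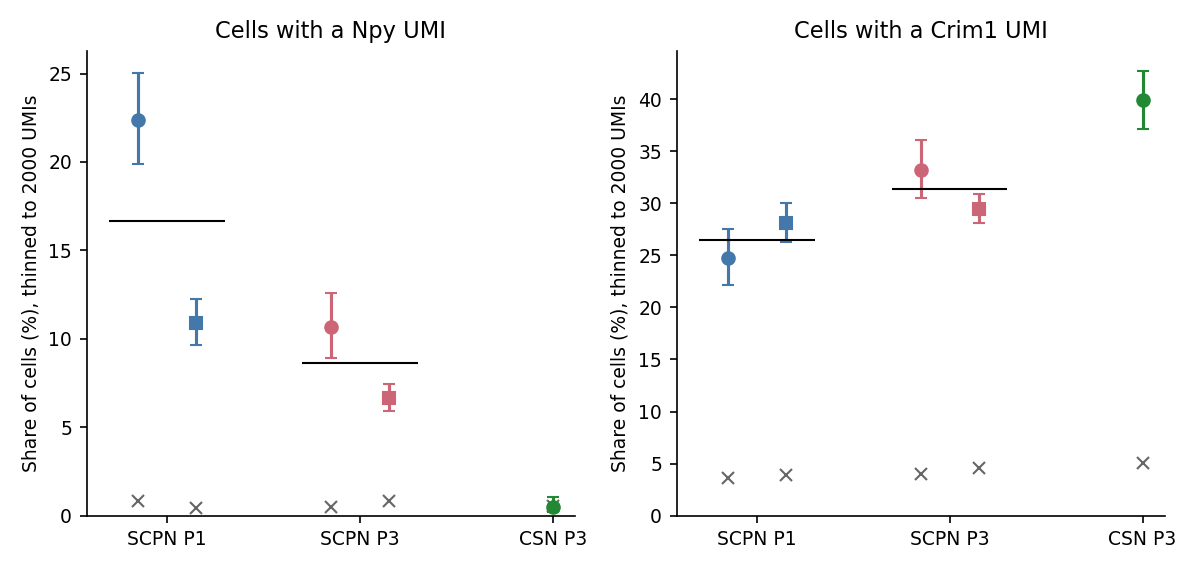
Share of SCPN-like cells (%) with at least 1 Npy UMI (left) or Crim1 UMI (right) after thinning to 2000 UMIs: circles are replicate 1, squares replicate 2, bars exact binomial 95% intervals, black lines SCPN group means and grey crosses the microglia-like share of the same sample. CSN sits at 0.49% for Npy, level with the crosses, and at 39.9% for Crim1, above the 4 SCPN samples.

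Npy and Crim1 were found together in the same cell slightly less often than independent detection would give. Over the 4 SCPN samples together, a sum made after the values were seen, 219 double-positive cells stood against 253 expected within the samples, a ratio of 0.866 (0.756 to 0.986). The ratio of observed to expected double-positive cells was 0.897 (95% interval 0.674 to 1.17; 52 cells) and 0.830 (0.633 to 1.07; 59 cells) at P1, and 0.845 (0.588 to 1.17; 34 cells) and 0.884 (0.696 to 1.11; 74 cells) at P3. It lay under 1 in all 4 SCPN samples, with means of 0.863 ± 0.0474 at P1 and 0.865 ± 0.0277 at P3 (SD, n = 2 each), and each sample's own interval included 1. Without thinning, P3 replicate 1 stood at 1.07 (0.909 to 1.24), the other 3 at 0.871 to 0.902, and the 4 together at 0.931 (0.854 to 1.01). CSN had 1 double-positive cell, for a ratio of 0.418 (0.0106 to 2.32). When a positive cell needed at least 2 UMIs, the SCPN ratios were 0.543, 0.388, 0.739 and 0.618, and the interval in P1 replicate 2 (0.126 to 0.904) excluded 1. At a finer clustering the intervals of 3 SCPN samples excluded 1, with ratios of 0.712 and 0.719 at P1 and 0.598 in P3 replicate 1, against 0.882 in P3 replicate 2.

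From P1 to P3, 2 of 23 channel genes, 2 of 31 postsynaptic and 4 of 25 presynaptic genes rose in SCPN-like cells, and 2 of 20 genes of immature neurons fell. These 4 lists were called, and each call was lost with an estimated correlation (adjusted p from 0.181 to 0.401). Pdgfb, a platelet-derived growth factor subunit (ENSMUSG00000000489, chromosome 15, positions 79995874 to 80014977, minus strand), rose by 3.53 ± 0.29 on the log2 scale (SE, 2 samples per age). Slc6a7, the brain proline transporter gene, rose by 2.85 ± 0.23 and Snhg11, a small nucleolar RNA host gene (ENSMUSG00000044349, chromosome 2, positions 158375638 to 158386145, plus strand), by 2.50 ± 0.26. Cartpt, the precursor of CART peptides (ENSMUSG00000021647, chromosome 13, positions 99898489 to 99901091, minus strand), rose by 2.17 ± 0.31. Igfbpl1, a gene of newborn neurons (ENSMUSG00000035551, chromosome 4, positions 45809468 to 45826923, minus strand), fell by 2.90 ± 0.31. Igf2bp1, which encodes an RNA-binding protein of fetal tissues, fell by 2.85 ± 0.42 and Npy by 1.80 ± 0.35. Of 14285 genes tested, 228 changed, with 143 that rose and 85 that fell, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That division moved with the samples and cells used: the part that rose, 62.7%, ran from 37.9% without P1 replicate 2 to 91.1% without cluster 25.

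All 228 moved the same way within both description codes, 2012 and 2106, that the labels give the replicates. The genes were called from these same samples, so this is not an independent replication. Within 2012 and 2106, the log2 changes were 4.06 and 3.004 for Pdgfb, 3.11 and 2.65 for Slc6a7, 2.96 and 2.08 for Snhg11, 1.60 and 2.85 for Cartpt, -2.77 and -2.94 for Igfbpl1, and -2.05 and -1.38 for Npy. The other named genes that rose were Rasal1 (3.03 ± 0.34), a Ras GTPase activator, Lynx1 (2.82 ± 0.38), a brake on nicotinic receptors, and Creg2 (2.24 ± 0.20). Icam5 (2.16 ± 0.39), an adhesion protein of forebrain dendrites, rose too, with Tmem132b (1.99 ± 0.29), Cpne6 (1.96 ± 0.17), the neurofilament gene Nefh (1.92 ± 0.26) and the kinase gene Camk2d (1.88 ± 0.23). Those that fell were Fst (-2.40 ± 0.44), which encodes follistatin, Trp53i11 (-2.02 ± 0.21), the cell cycle inhibitor Cdkn1c (-1.87 ± 0.34) and Cdk2ap1 (-1.87 ± 0.33). So did the histone H3.3 gene H3f3a (-1.70 ± 0.24), the Wnt antagonist Sfrp1 (-1.52 ± 0.22), Rnf182 (-1.36 ± 0.20), the transcription factor gene Sox4 (-1.35 ± 0.23) and Dctpp1 (-1.33 ± 0.24). Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg ran from 0.00803 for Pdgfb to 0.0496 for Npy.

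**Figure D2:**
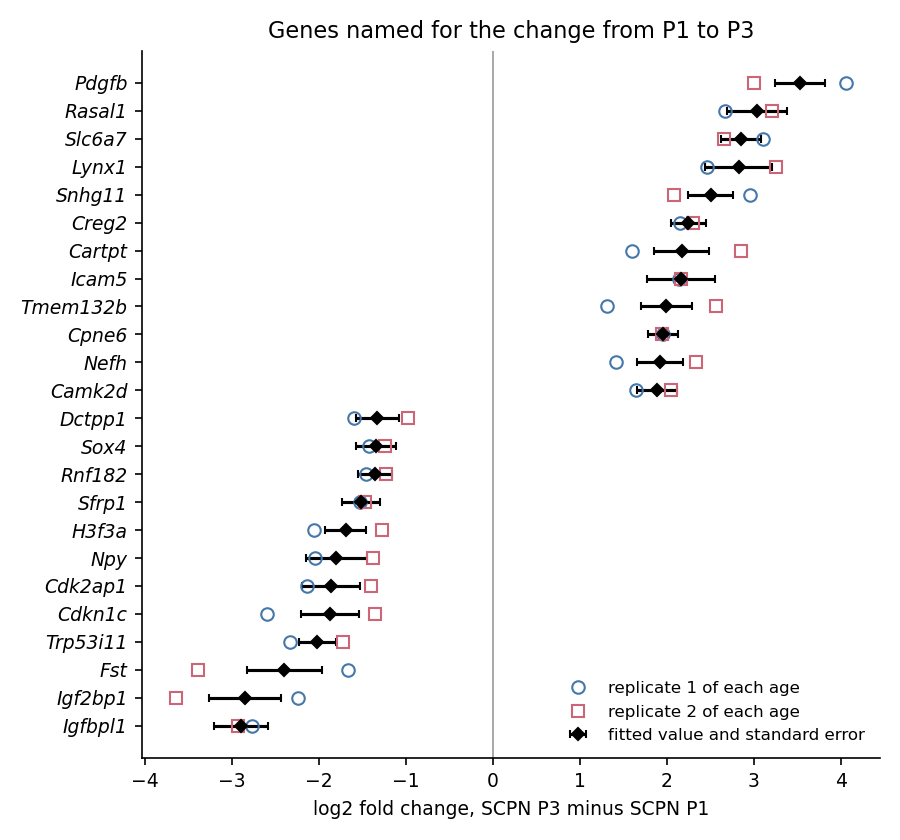
Log2 fold change of SCPN P3 over P1 (x axis) for 24 named genes in SCPN-like cells; blue circles and red squares are the ratios within replicate numbers 1 and 2, black diamonds the fitted value with its SE. Both ratios lie on the same side of 0 for each gene, as the rule that chose the genes required. Fitted values run from Pdgfb at 3.53 to Igfbpl1 at -2.90.

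The voltage-gated sodium and potassium channel list was called upward: 2 of 23 rose over all genes and 14 when adjusted over the list alone. Among them were the potassium channel genes Kcna1 (2.12 ± 0.33) and Kcna2 (0.94 ± 0.18), while Hcn2 (0.88 ± 0.17, adjusted p = 0.0511 by edgeR with Benjamini-Hochberg) did not pass. The list passed camera with a preset correlation (adjusted p = 4.73e-08), and not with an estimated correlation (adjusted p = 0.181). Of the postsynaptic receptor and scaffold list, 2 of 31 rose and 12 when adjusted over the list alone (adjusted p = 6.25e-07, or p = 0.181 with an estimated correlation). Examples are Camk2a (1.25 ± 0.22) and the GABA-A receptor gene Gabrb1 (1.16 ± 0.19). Of the presynaptic list, 4 of 25 rose and 7 when adjusted over the list alone (adjusted p = 1.16e-06, or p = 0.389 with an estimated correlation). They include Syn2 (1.43 ± 0.20) and the vesicular glutamate transporter gene Slc17a7 (1.35 ± 0.19). The neuropeptide list had 3 of 15 that rose and 1 that fell, and 6 and 1 when adjusted over the list alone (adjusted p = 0.00674, or p = 0.401 with an estimated correlation). Cartpt, Scg2 (1.36 ± 0.18) and the somatostatin receptor gene Sstr2 (1.16 ± 0.18) rose and Npy fell. Of axon guidance genes, 4 of 42 rose and 5 when adjusted over the list alone (adjusted p = 0.00616, or p = 0.401 with an estimated correlation). The 4 were Slit2 (1.48 ± 0.20), Unc5c (1.23 ± 0.20), Plxna4 (1.20 ± 0.23) and Epha4 (1.05 ± 0.18). Of cell adhesion genes, 2 of 28 rose and 3 when adjusted over the list alone, with Cdh20 (1.18 ± 0.22) and Cntn1 (1.16 ± 0.19; adjusted p = 0.00395, or p = 0.434 with an estimated correlation).

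The immature neuron and growth cone list was called downward, with 2 of 20 that fell and 6 when adjusted over the list alone (adjusted p = 0.000289, or p = 0.401 with an estimated correlation). The 2 were Sox4 and Sox11 (-1.25 ± 0.20), while Gap43 stood at -0.33 and did not pass. The corticothalamic identity list was called downward with 0 of 10 that passed over all genes and 1 that fell when adjusted over the list alone. Its adjusted p was 0.0384, or p = 0.401 with an estimated correlation, and Rprm led it at -1.12 ± 0.22. Genes of subcerebral identity showed no common direction: 1 of 16 rose, Parm1 (1.80 ± 0.33), and 2 rose and 1 fell when adjusted over the list alone (adjusted p = 0.853). Bcl11b and Fezf2, regulators of this fate, stood at -0.47 each, Ldb2 at -0.20, Crym at 0.20 and Crim1 at 0.33 (0.62 and 0.04 within the codes), and none passed. Of 6 corticospinal and cortico-brainstem subtype genes, Cartpt and Lum (1.45 ± 0.27) rose and Npy fell, also when adjusted over the list alone (adjusted p = 0.162). How the study chose such genes is not given in the sources used here, so that list is no independent evidence of a direction. Callosal identity was not called, with 0 of 14, and 1 that fell when adjusted over the list alone (adjusted p = 0.286). Nor were cholesterol synthesis (0 of 20 both ways, adjusted p = 0.730), areal patterning (0 of 13, 0.162) and immediate early genes (0 of 14, 0.730). Tle4 (-0.28), Sox5 (-0.36), Klhl14 (-0.33), Cbln1 (0.52) and Sst (1.89 ± 0.50) did not pass. Endothelial markers (median log2 change 1.36) and erythroid markers (2.12) stood above 0 with the same samples (adjusted p = 0.0625 each by camera), and the ribosomal cluster 25 was the larger at P1.

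The count was 2463 with the description code as a block, 81 without P1 replicate 1 (62 of the 228 genes among them), 1122 without P1 replicate 2, 66 without P3 replicate 2 (59 among them) and 56 without cluster 25, an alternative chosen after seeing the data, and of the 43 named genes that passed, 24 were lost without P1 replicate 1, 21 without P3 replicate 2, 4 without P3 replicate 1, 9 without CSN and 28 without cluster 25. Npy was among the lost, at -1.15 without P1 replicate 1 (adjusted p = 0.0828), -1.60 without P3 replicate 2 (0.117), -1.80 without CSN (0.0548), and also without cluster 25 (0.103; edgeR, Benjamini-Hochberg), and leaving out P1 replicate 1 ended the calls of the axon guidance (adjusted p = 0.0820), adhesion (0.0855) and corticothalamic lists (0.0855), P3 replicate 2 those of the neuropeptide and adhesion lists (0.0886 each), and P1 replicate 2 (0.0792) or P3 replicate 1 (0.160) that of the corticothalamic list.

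At P3, SCPN-like cells of the CSN sample held far less Npy than those of the SCPN samples, with less Klhl14, although no gene passed the test. Cluster 12, led by Npy, Klhl14 and Sema3e, held 11.4 and 5.40% of SCPN-like cells in the P3 samples and 0 of 1291 in CSN, which allows a share of up to 0.232%. The cluster was drawn partly from these genes, so its absence in CSN and the lower Npy and Klhl14 are not independent. Npy was 45.4-fold (30.6 to 70.3) and 33.4-fold (22.5 to 51.7) higher in P3 replicates 1 and 2 than in CSN in raw CPM, with 95% intervals for counting error only (25 Npy UMIs in CSN against 1826 and 2014). Klhl14, a ubiquitin ligase adaptor gene of the Kelch-like family (ENSMUSG00000042514, chromosome 18, positions 21550377 to 21654718, minus strand), was 19.9-fold (10.7 to 41.9) and 8.41-fold (4.48 to 17.8) higher in the P3 replicates. Crim1 stood at 329 CPM in CSN against 250 and 198 CPM in the P3 replicates.

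**Figure D3:**
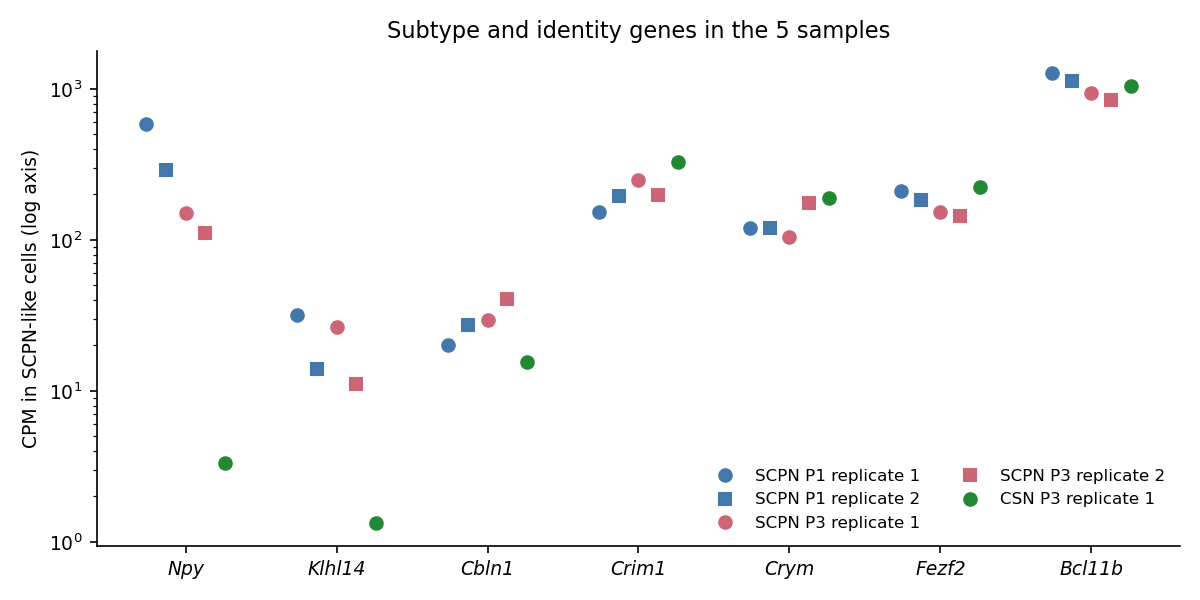
Raw CPM (log axis) of Npy, Klhl14, Cbln1, Crim1, Crym, Fezf2 and Bcl11b summed over SCPN-like cells in each of the 5 samples. Npy runs from 585 in P1 replicate 1 to 3.33 in CSN, while Bcl11b stays between 850.2 and 1270.2.

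With 1 CSN sample, assumed to vary like the SCPN samples, edgeR's quasi-likelihood test with Benjamini-Hochberg called 0 of 14285 genes, with 526 at an unadjusted p under 0.05, and DESeq2 called 30. With the description code as a block, which CSN shares with the second SCPN replicates and whose meaning the labels do not give, edgeR called 191. Below SCPN, the smallest p was that of Stxbp6 (ENSMUSG00000046314, chromosome 12, positions 44852484 to 45074709, minus strand), with a log2 difference of -3.48 ± 0.34 (adjusted p = 0.0737). Next were Npy (-5.30 ± 0.61, 0.128), the receptor tyrosine kinase gene Kit (-2.40 ± 0.29, 0.128) and Wls (-2.44 ± 0.32, 0.135), which exports Wnt proteins. Above SCPN were Ptgds (5.25 ± 0.61, 0.135), Prss35 (1.65 ± 0.23, 0.149), Lsm4 (1.55 ± 0.22, 0.156), the haemoglobin gene Hba-a1 (1.39 ± 0.22, 0.273) and Eef2kmt (2.49 ± 0.43, 0.346). Ptgds, a prostaglandin D synthase gene of the meninges and glia, had 0 and 0 UMIs at P1, 2 and 12 at P3 and 131 in CSN. The areal gene Lmo4 stood at -2.56 ± 0.36 (adjusted p = 0.149), Klhl14 at -3.80 ± 0.86 (0.785), Cbln1 at -1.18 ± 0.30 (0.896) and Crim1 at 0.55 ± 0.24 (1.000). Fezf2 (0.60), Crym (0.43), Tle4 (0.28), Bcl11b (0.22), Sox5 (-0.01), Lum (-0.13), Ldb2 (-0.16), Gap43 (-0.38) and Sst (-2.02) did not pass either.

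Of the 14 gene lists, camera called 0 in this comparison. The subtype genes came nearest, below SCPN with unadjusted p = 0.00433 and adjusted p = 0.0606 (p = 0.669 with an estimated correlation), and 3 of the 6 were lower when adjusted over the list alone. Neuropeptides followed (adjusted p = 0.123, 1 of 15 lower when adjusted over the list alone). Then came subcerebral identity, above SCPN (0.149, 0 of 16), and callosal identity, below it (0.226, 1 of 14 lower when adjusted over the list alone). Postsynaptic genes (0.246), immediate early genes (0.281), immature neuron, presynaptic and adhesion genes (0.480 each), corticothalamic identity (0.657), axon guidance, channels, cholesterol synthesis and areal patterning (0.899 each) lay further off. Adjusted over the list alone, 1 axon guidance gene was higher, and 1 areal gene was higher and 1 lower. The list test and the list's own values differed in sign for axon guidance (median 0.01, mean -0.08, test upward), channels (0.08, -0.12, downward), cholesterol synthesis (-0.06, -0.01, upward) and areal patterning (-0.10, -0.11, upward). Among markers of other cell types, the 4 measured Cajal-Retzius genes were lower in CSN (median -1.13, adjusted p = 0.0106, or p = 0.516 with an estimated correlation), 1 of them when adjusted over the list alone. Endothelial-like cells were the larger share there.

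The count became 4 without P1 replicate 1, 27 without P1 replicate 2, 18 without P3 replicate 1 and 6 without P3 replicate 2, Npy passing each time at log2 differences of -5.06 to -5.50 (adjusted p 0.00286, 2.37e-05, 0.000530 and 0.0147 in that order; edgeR, Benjamini-Hochberg), Stxbp6, Kit and Ptgds likewise, while the subtype list passed without P1 replicate 2 (0.0456) and P3 replicate 1 (0.0200) and the neuropeptide list without P3 replicate 1 (0.00172). Npy also passed under DESeq2, with no count filter, after thinning, at a finer clustering and at a mitochondrial limit of 5%, and the log2 difference of Npy was -1.68 over all cells that pass the filters.

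SCPN-like cells with an Npy UMI held more Klhl14 and Sema3e than the other SCPN-like cells, and less St6galnac5 and Crym. Klhl14 was higher in Npy-positive cells by 4.34 ± 0.17 on the log2 scale (SE, 4 SCPN samples), Sema3e, a secreted semaphorin, by 2.63 ± 0.12 and Fst by 2.81 ± 0.20. St6galnac5, a sialyltransferase gene (ENSMUSG00000039037, chromosome 3, positions 152817081 to 152982246, minus strand), was lower by -3.04 ± 0.22. Crym, which encodes a thyroid hormone-binding protein (ENSMUSG00000030905, chromosome 7, positions 120186380 to 120202111, minus strand), was lower by -2.70 ± 0.18. So were Cartpt by -2.54 ± 0.26 and the secreted Wnt gene Wnt5a (ENSMUSG00000021994, chromosome 14, positions 28504750 to 28527448, plus strand) by -3.34 ± 0.49. Of 9547 genes tested, 683 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg and the sample as a block, 364 higher and 319 lower. In all 4 samples, 634 had the same sign. Npy itself was left out, and cluster 12, in which 78.5% of thinned cells had an Npy UMI, held most of the positive cells against 0.539 to 13.7% in the other SCPN-like clusters.

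Other named genes that were higher included Il1rap (3.11 ± 0.25), the titin gene Ttn (2.76 ± 0.20), Wls (2.33 ± 0.16), Cachd1 (2.15 ± 0.23) and Igfbp5 (2.14 ± 0.13), an IGF-binding protein. So were Dkk3 (2.10 ± 0.17), Vwc2l (2.08 ± 0.18), Trhde (2.06 ± 0.14) and Pantr1 (2.05 ± 0.10). Other named genes that were lower included Rspo3 (-3.32 ± 0.35), a Wnt enhancer, Nr4a3 (-2.93 ± 0.47), Slit3 (-2.81 ± 0.52) and Astn2 (-2.69 ± 0.44). Vgf (-2.60 ± 0.25), a secreted neuropeptide precursor, was lower as well, with Nrp2 (-2.43 ± 0.35), Vstm2b (-2.32 ± 0.22) and the synaptotagmin gene Syt4 (-2.21 ± 0.09). Adjusted p by edgeR with Benjamini-Hochberg reached 2.31e-23 for Klhl14 and Syt4, 6.38e-21 for Sema3e and 5.59e-16 for Crym. The spread behind these p-values and SEs is partly pooled over genes, so an SE need not show how far the samples lay apart. The log2 ratios of the 4 samples were 3.47, 1.97, 1.73 and 1.71 for Igfbp5. For Nrp2 they were -1.25, -1.42, -1.80 and -6.05.

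**Figure D4:**
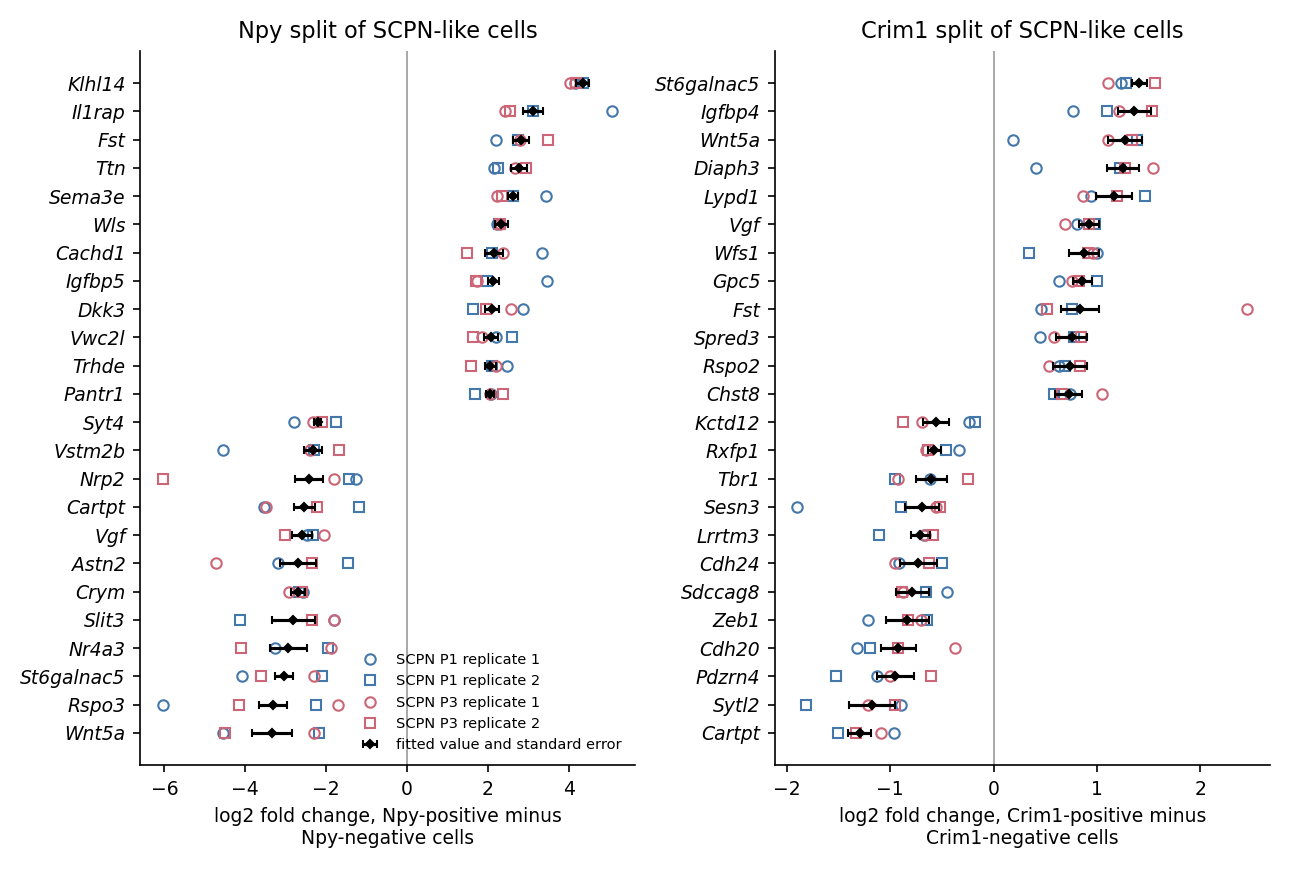
Log2 ratio of positive over negative SCPN-like cells (x axis) for 24 named genes each in the Npy split (left) and the Crim1 split (right); open symbols are the 4 SCPN samples and black diamonds the fitted value with its SE. Klhl14 leads the Npy split at 4.34 and St6galnac5 the Crim1 split at 1.41, while St6galnac5 lies at -3.04 in the Npy split.

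The cholesterol synthesis list was lower in Npy-positive cells: 4 of 19 passed, and 8 when adjusted over the list alone (camera adjusted p = 0.000270, or p = 0.591 with an estimated correlation). The 4 were Hmgcs1 (-0.36 ± 0.07), Sqle (-0.47 ± 0.08), Fdps (-0.40 ± 0.12) and Hsd17b7 (-0.56 ± 0.18). The axon guidance list was called upward with members going both ways, 11 of 37 higher and 4 lower, and 15 and 7 when adjusted over the list alone (adjusted p = 0.0463, or p = 0.591 with an estimated correlation). Sema3e, Sema3a (1.44 ± 0.14), Sema3c (0.89 ± 0.11) and Epha4 (0.96 ± 0.09) were higher and Slit3 and Nrp2 lower. Callosal identity had 3 of 8 higher and 1 lower, and 4 and 1 when adjusted over the list alone (adjusted p = 0.194). Pou3f2 (1.46 ± 0.10) and Pou3f3 (1.34 ± 0.09) were among the higher and Rorb (-0.92 ± 0.11) lower. Subcerebral identity had 5 of 15 higher and 7 lower, also when adjusted over the list alone (adjusted p = 0.459). Fezf2 (0.47 ± 0.10), Sox5 (0.59 ± 0.08) and Pou3f1 (0.59 ± 0.09) were higher. Crym, Cntn6 (-1.32 ± 0.13) and Crim1 (-0.42 ± 0.10, adjusted p = 0.00492 by edgeR) were lower, while Bcl11b (-0.07) and Ldb2 (0.07) did not pass. The adhesion list split 7 higher and 11 lower of 26, and 9 and 12 when adjusted over the list alone (0.459). Cdh12 stood at 1.78, Pcdh9 at 1.72 ± 0.10, Cdh4 at 1.14 and Cdh13 at -2.12 ± 0.16.

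Of the other lists, none called, subtype genes had 1 of 5 higher, Klhl14, and 2 lower, Cartpt and Crim1, with 2 and 3 when adjusted over the list alone (adjusted p = 0.969). Cbln1 (-0.62, 0.0997) and Lum (0.79 ± 0.29, 0.104; edgeR) did not pass. Areal genes had 3 of 10 higher, Nr2f1 (0.92 ± 0.14) among them, and 1 lower, Lmo4 (-0.91 ± 0.16), with 5 and 1 when adjusted over the list alone (0.380). Corticothalamic genes had 1 of 7 higher, Rprm (0.71 ± 0.09), and 2 lower, Nfia (-1.45 ± 0.15) among them, also when adjusted over the list alone (0.774), with Tle4 at 0.19. Neuropeptides had 2 of 7 higher, Adcyap1 (0.77 ± 0.17) among them, and 2 lower, Vgf and Cartpt. The numbers were 3 and 2 when adjusted over the list alone (0.929). Adcyap1 passed without the same sign in every sample, at 1.39 and 1.09 at P1 and -0.93 and 0.52 at P3. Channels had 3 of 20 higher and 1 lower, Scn1a (-0.48 ± 0.11), with 4 and 1 when adjusted over the list alone (0.419). Presynaptic genes had 2 of 23 higher, Cplx2 (1.19 ± 0.09) and Pclo (0.81 ± 0.07), and 4 lower, with Syt4 and Sv2b (-0.82 ± 0.14), and 3 and 6 when adjusted over the list alone (0.774). Postsynaptic genes had 3 of 30 higher, with Gria4 (0.73 ± 0.16), and 6 lower, with Gabra2 (-0.75 ± 0.13), and 4 and 10 when adjusted over the list alone (0.419). Immature neuron genes had 2 of 20 lower, Gap43 (-0.57 ± 0.07) and Islr2 (-0.41 ± 0.08), also when adjusted over the list alone (0.380). Immediate early genes had 0 of 5 (0.774). Median, mean and test differed in sign for the subtype (-0.42, 0.31, upward), corticothalamic (0.17, -0.14, upward), neuropeptide (0.20, -0.45, downward) and immediate early lists (0.19, -0.03, downward). Of other cell types' markers, the 2 measured fibroblast genes, Lum among them, were higher (adjusted p = 0.00455, or p = 0.546 with an estimated correlation). Of these, 1 passed over all genes and 2 when adjusted over the list alone.

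DESeq2 called 356 genes and a fit without the sample block 132. The axon guidance call was lost without P1 replicate 1 (adjusted p = 0.330), P1 replicate 2 (0.154), P3 replicate 1 (0.0740) or P3 replicate 2 (0.0553), callosal identity passed without P3 replicate 2 (0.0436), and of 56 named genes that passed, 2, 4, 1 and 2 were lost without these 4 samples in turn, from among Fdps, Hsd17b7, Adcyap1, Scn1a and Crim1.

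Crim1-positive cells differed from Crim1-negative cells by smaller amounts, but the splits do not part cells equally cleanly. In the 4 SCPN samples the Crim1 share was 44.0 to 70.4% without thinning and 24.8 to 33.2% with it. The Npy share was 7.91 to 25.6% and 6.65 to 22.4%. Many Crim1-negative cells thus had a Crim1 UMI before thinning, and how far this explains the smaller amounts was not tested. St6galnac5 was higher by 1.41 ± 0.07 on the log2 scale (SE, 4 SCPN samples), Igfbp4, an IGF-binding protein, by 1.36 ± 0.16, Wnt5a by 1.27 ± 0.16 and the formin gene Diaph3 by 1.25 ± 0.15. Cartpt was lower by -1.29 ± 0.11, Sytl2 by -1.17 ± 0.22, Rorb, a nuclear receptor gene of upper-layer neurons, by -0.47 ± 0.06 and Npy by -0.32 ± 0.06. Of 10276 genes tested, 324 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg and the sample as a block, 206 higher and 118 lower. In all 4 samples, 268 had the same sign. Crim1 was left out of the test, and the share of cells with a Crim1 UMI ran from 16.3% in cluster 3 to 52.8% in cluster 13.

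Other named genes that were higher were Lypd1 (1.16 ± 0.17), Etv5 (1.04 ± 0.23), an ETS factor gene, and Vgf (0.92 ± 0.10). Also higher were Wfs1 (0.88 ± 0.14), the glypican gene Gpc5 (0.86 ± 0.09), Fst (0.84 ± 0.18), Spred3 (0.76 ± 0.15) and Rspo2 (0.74 ± 0.16). Others that were lower were Pdzrn4 (-0.95 ± 0.18), Cdh20 (-0.92 ± 0.17), Zeb1 (-0.83 ± 0.21), Sdccag8 (-0.78 ± 0.16) and Cdh24 (-0.73 ± 0.18). Lower too were Lrrtm3 (-0.71 ± 0.09), Sesn3 (-0.69 ± 0.16), Tbr1 (-0.60 ± 0.15), the relaxin receptor gene Rxfp1 (-0.57 ± 0.07) and Kctd12 (-0.56 ± 0.13). Adjusted p by edgeR with Benjamini-Hochberg reached 1.55e-27 for St6galnac5 and 7.98e-15 for Cartpt, and was 5.01e-05 for Npy. Lum (-0.74 ± 0.22, adjusted p = 0.0402) and Cbln1 (0.61 ± 0.14, 0.00239) passed without the same sign in every sample. Klhl14 (-0.62 ± 0.20, 0.0693), Gap43 (-0.10), Ldb2 (-0.09), Bcl11b (-0.05), Fezf2 (-0.02) and Tle4 (0.02) did not pass.

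The cholesterol synthesis list was higher in Crim1-positive cells, with 5 of 19 that passed and 12 when adjusted over the list alone (camera adjusted p = 8.08e-05, or p = 0.218 with an estimated correlation). Its members included Cyp51 (0.21 ± 0.05), Hmgcs1 (0.19 ± 0.04) and Sqle (0.18 ± 0.05). Postsynaptic genes were higher too, 5 of 30 and 6 when adjusted over the list alone (adjusted p = 0.0132, or p = 0.218 with an estimated correlation). Examples were Gabra2 (0.46 ± 0.07) and Gria3 (0.36 ± 0.08). Subtype genes went downward, with 1 of 5 higher, Cbln1, and 3 lower, Cartpt, Lum and Npy, and 1 and 4 when adjusted over the list alone (adjusted p = 0.0138, or p = 0.218 with an estimated correlation). Axon guidance genes had 8 of 38 higher, with Efna5 (0.73 ± 0.07), Sema3c (0.42 ± 0.07) and Ephb1 (0.30 ± 0.05), and 2 lower, with Sema6d (-0.26 ± 0.06). The numbers were 11 and 5 when adjusted over the list alone (adjusted p = 0.0436, or p = 0.218 with an estimated correlation). Adhesion genes had 7 of 26 higher, with Pcdh17 (0.39 ± 0.04), Cntn1 (0.37 ± 0.05) and Pcdh19 (0.34 ± 0.05), and 2 lower, with Cdh20. The numbers were 8 and 4 when adjusted over the list alone (adjusted p = 0.0436, or p = 0.469 with an estimated correlation).

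The other lists were not called. Subcerebral identity had 4 of 14 higher, with Igfbp4, Chst8 (0.73 ± 0.13) and Crym (0.40 ± 0.07), and 3 lower, with Sox5 (-0.33 ± 0.05). They were 5 and 3 when adjusted over the list alone (adjusted p = 0.325). Callosal identity had 2 of 9 higher and 1 lower, Rorb, with 2 and 2 when adjusted over the list alone (0.457). Corticothalamic identity had 1 of 8 higher, Zfpm2 (0.72 ± 0.17), and 2 lower, Tbr1 and Rprm (-0.26 ± 0.07), with 2 and 2 when adjusted over the list alone (0.503). Areal genes had 2 of 10 higher, Etv5 and Efna5, and 2 lower, with Bhlhe22 (-0.44 ± 0.06), and 2 and 3 when adjusted over the list alone (0.639). Neuropeptides had 2 of 9 higher, with Vgf, and 3 lower, with Scg2 (-0.45 ± 0.09), and 4 and 3 when adjusted over the list alone (0.503). Immature neuron genes had 2 of 20 higher, with Cd24a (0.20 ± 0.05), and 2 lower, and 2 and 5 when adjusted over the list alone (0.503). Presynaptic genes had 1 of 23 higher, Syt4 (0.24 ± 0.03), and 1 lower, Cplx2 (-0.29 ± 0.06), and 3 and 1 when adjusted over the list alone (0.754). Channels had 0 of 20 (0.503) and immediate early genes 0 of 8 (0.143), also when adjusted over the list alone. Median, mean and test differed in sign for subcerebral identity (-0.01, 0.10, upward) and presynaptic genes (-0.01, -0.000995, upward). No marker list of another cell type was called. The lowest adjusted p was 0.0817, for the subcerebral markers themselves.

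The count was 126 without P3 replicate 2 (109 of the 324 among them), 181 without P1 replicate 2 and 207 without P1 replicate 1. It was 159 with at least 2 Crim1 UMIs per positive cell. DESeq2 called 83, but gave an adjusted p to only 713 genes, where edgeR tested 10276. Without the sample block edgeR called 0 (139 at an unadjusted p under 0.05). Of 50 named genes that passed, 20 were lost without P3 replicate 2, 9 without P1 replicate 2, 3 without P1 replicate 1 and 1 without P3 replicate 1. The postsynaptic and subtype calls were lost without P1 replicate 2 (adjusted p = 0.0593 each) and P3 replicate 2 (0.0694 and 0.0508), and the axon guidance and adhesion calls without any 1 of the 4 samples (axon guidance 0.0532, 0.104, 0.0910 and 0.137), while that of cholesterol synthesis held in all 4.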

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

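The tests of a common slope, the restriction to divisions that part each pair of sums, and the alternatives tried for the difference between ages were chosen after the results were seen.

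The Npy split differed between P1 and P3 for 15 of 9547 genes by an interaction term (603 at an unadjusted p under 0.05, edgeR's quasi-likelihood test), 13 lower at P3 and 2 higher. The differences of log2 ratio, P3 minus P1, were -0.89 for Igfbp5, -0.83 for Serpine2, -1.94 for Tgfb2, -0.60 for Lrp1b, -0.62 for Pcsk2, -0.78 for Hs6st2, -1.56 for Unc5c, -1.48 for Adcyap1r1, -0.99 for Nrp1, -1.88 for Thrb, -0.62 for Pcdh9, 1.21 for Flrt2, -1.43 for Sidt1, 0.60 for Fth1 and -0.53 for Sorcs1. Tgfb2, a growth factor gene, was higher in Npy-positive cells of the P1 samples (0.18 and 0.25) and lower in those of the P3 samples (-1.83 and -1.64). Fth1, the ferritin heavy chain gene, went from -0.25 and -0.14 at P1 to 0.30 and 0.47 at P3. The count was 7 without P1 replicate 1, 26 without P1 replicate 2, 9 without P3 replicate 1, 7 without P3 replicate 2 and 5 without thinning, and DESeq2 called 0.

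A candidate explanation is that an Npy UMI marks Npy cells less well at P3, where Npy is lower. It was tested in a simple form, a shrinkage of each gene's log2 ratio by the same factor. Misplaced cells mix counts, not log2 ratios, so raised and lowered genes need not shrink by the same factor. Over the 672 other genes called in the split, the slope of P3 on P1 log2 ratios was 0.830 ± 0.0154 (SE across genes, which are not independent). Noise in the P1 ratios also lowers such a slope, so its value cannot by itself show weaker marking. With this slope taken off, 8 of the 15 differences no longer passed, Igfbp5 going from -0.89 ± 0.15 to -0.45 ± 0.14 and Pcdh9 from -0.62 ± 0.15 to -0.27 ± 0.14. For these weaker marking may be enough, while Adcyap1r1 (-1.48 ± 0.37 to -1.29 ± 0.34) and Sidt1 (-1.43 ± 0.36 to -1.03 ± 0.32) lost the call with little or moderate change. The other 7, Serpine2, Tgfb2, Unc5c, Nrp1, Thrb, Flrt2 and Fth1, still passed, which a shrinkage by the same factor forbids. Tgfb2 and Fth1 changed sign in both samples of each age, which mixing of positive and negative cells would not give. For the rest of the 7, unequal shrinkage was not tested, so weaker marking stays open. With the slope taken off 11 genes were called in all, 4 of them not among the 15. Age and the different clusters that hold most of the class at P1 and P3 stay open for these, untested.

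The 8 sums of each split are pairs of positive and negative cells of 4 samples, which the sample block keeps together. Of the divisions into 4 and 4, 8 part every pair, too few for a share under 0.05. For Npy the real one called 683 genes, the only 1 of the 8 with as many, against at most 0 in the others, and for Crim1 324, again 1 of 8, against at most 41. Over all 32 divisions that could be fitted, most of which break pairs (3 more could not be fitted), the highest others were 5 and 62.

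The Crim1 split differed between P1 and P3 for 1 of 10276 genes, Tshz2 (difference 1.65, adjusted p = 0.00370 by edgeR with Benjamini-Hochberg; 507 at an unadjusted p under 0.05), with log2 ratios of 0.27 and -1.24 at P1 and -1.60 and 0.65 at P3, so the replicates disagreed in sign at both ages. Without P1 replicate 2 and without P3 replicate 2 it was not among the genes called, and DESeq2 and edgeR without thinning each called 0.

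Of 117 groups of 4 samples, 6 had a sample set apart, where about 1 in 20 groups, or 5.85, would by chance; the value is the gap to the nearest sample over the whole range. In the Npy split, P3 replicate 2 stood apart for Tle4 (0.884; log2 ratio -0.51 against 0.48, 0.39 and 0.37) and Nrp2 (0.886; -6.05), and P1 replicate 1 for Igfbp5 (0.8502; 3.47). In the Crim1 split, P1 replicate 2 stood apart for Wfs1 (0.866; 0.34) and Rorb (0.932; -0.27), and P3 replicate 1 for Fst (0.852; 2.45).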

How the results depend on the processing

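Chosen after the results were seen were the removal of the highest 5% of doublet scores, the mitochondrial limit of 20%, the removal of cluster 25, and shares and lists without each sample. The alternatives of the tests of age in the splits and in callosal-like cells were chosen then too. With 2 samples per age and 1 in CSN, the counts of genes moved with many of the settings. Where leaving out a sample left 1 at an age, that sample was assumed to vary like the others. Of the named genes that passed, 601 values over the alternatives kept sign and call for P3 against P1, 172 lost the call and 1 turned. For Npy 736 kept both and 46 lost the call, and for Crim1 548 and 116, with 0 turned in either. Of genes that had not passed, 220 values for P3 against P1, 289 for CSN against SCPN, 68 for Npy and 62 for Crim1 kept sign and side, and 34, 73, 0 and 4 came to pass. Lists kept both in 89, 78, 65 and 58 values, in the same order. For a log2 fold of 1, simulated data gave 25% recovery in the CSN comparison, which has 1 sample on a side, and how much of this comes from depth was not tested. The cause was not tested for any value below unless fewer samples or genes are its own construction.

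For P3 against P1, where 228 genes were called, DESeq2 called 760 and edgeR with no count filter 1647. Excitatory neurons gave 1549, called doublets kept 499, the highest 5% of doublet scores removed 458, a mitochondrial limit of 5% 76 and cells without cluster 25 56. Clusters were drawn and named anew when called doublets were kept, so more than the doublets changed. The cells in all went from 3522 to 3535 and from 4674 to 4677 at P1. The SCPN-like cells went from 1079 to 866 and from 2550 to 2271 at P1. At P3 they went from 1153 to 1150 and from 4632 to 4605. Over all cells that pass the filters, edgeR called 0, with 2238 at an unadjusted p under 0.05. Without each sample the count ran from 66 to 1122. For CSN against SCPN, where edgeR called 0, DESeq2 called 30 and no filter 125. Thinning and a resolution of 2 gave 5 each, a mitochondrial limit of 5% gave 4, and counts without each sample ran from 4 to 27. The Npy split of 683 went to 356 with DESeq2. The Crim1 split of 324 went to 83 with DESeq2, which gave an adjusted p to only 713 genes. Of these 83 calls, 81 were among the 324. The count was 159 with at least 2 UMIs and between 126 and 275 without each sample. The part of calls that were higher was 62.7% for P3 against P1. It was 40.0% in excitatory neurons, 50.5% with DESeq2, 51.3% with no filter, 49.0% with the code as a block, 82.9% at a mitochondrial limit of 5% and 91.1% without cluster 25. Without P1 replicates 1 and 2 it was 82.7 and 37.9%, and without P3 replicate 2 84.8%. It was 53.3% for the Npy split and 38.1% with no filter or 64.4% without the sample block.

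The description code, which for SCPN goes with the replicate number and which CSN replicate 1 shares with the SCPN replicates 2, was tried as a replicate block. Deviations from the group means correlated at 0.434 over 8069 genes between same-numbered samples, but 2 pairs cannot show pairing and the labels do not say what the codes mean. Whether a code marks a shared preparation stays open. With this block 2463 genes were called for P3 against P1 and 191 for CSN against SCPN, and 6 lists for CSN against SCPN in place of 0. It turned 4 lists of that comparison, immature neurons (adjusted p = 0.972), axon guidance (0.748), cholesterol synthesis (0.748) and areal patterning (0.534), and the log2 differences of Ldb2 (0.0902) and Sox5 (0.15). Without the sample block of the splits, the Npy count was 132 and the Crim1 count 0, with 139 at an unadjusted p under 0.05 by edgeR. DESeq2 with the block called 83 of the 713 genes that it gave an adjusted p in the Crim1 split.

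The share of SCPN-like cells was 24.1% at P1, 18.4% at P3 and 36.3% in CSN at a mitochondrial limit of 5%. At a resolution of 2 it was 24.7% at P3 and 36.5% in CSN. In CSN it was 47.0% with the highest doublet scores removed and 60.2% at a limit of 20%. Npy was found in 12.3% of SCPN-like cells at P3 without thinning, and in 0.0822% in CSN with at least 2 UMIs. Crim1 was found in 48.1, 57.2 and 64.7% without thinning at P1, at P3 and in CSN. With at least 2 UMIs the shares were 6.52, 9.20 and 13.8%, and at a resolution of 2 they were 30.3, 37.4 and 45.6%. The ratio of observed to expected cells with both was 0.4657 at P1, 0.679 at P3 and 0 in CSN with at least 2 UMIs. At a resolution of 2 it was 0.715 and 0.740 at P1 and P3. It was 0.763 at P1 with called doublets kept, and at P3 0.978 without thinning and 0.826 with the highest doublet scores removed.

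With an estimated correlation 0 lists were called by camera for P3 against P1 and 0 in either split, in place of 8, 2 and 5. In excitatory neurons 0 were called in the Npy split and 9 in the Crim1 split. There the test turned direction for areal patterning in CSN against SCPN (adjusted p = 0.252). In the Npy split it turned for subtype and callosal genes (0.987 each), postsynaptic genes (0.377) and neuropeptides (0.380), and in the Crim1 split for corticothalamic (0.177) and areal genes (0.636). Without each sample, 5 to 8 lists were called for P3 against P1, 0 to 2 for CSN against SCPN, 1 to 2 in the Npy split and 1 to 3 in the Crim1 split. Some lists turned direction without a sample, with these ranges of adjusted p. For P3 against P1 they were subcerebral (0.557 to 0.860), cholesterol (0.455 to 0.769) and immediate early genes (0.0855 to 0.969). For CSN against SCPN they were axon guidance (0.903 to 0.992), cholesterol and areal (0.514 to 0.976 each) and adhesion genes (0.0747 to 0.794). In the Npy split they were subtype (0.775 to 0.958), corticothalamic (0.566 to 0.797), neuropeptide (0.333 to 0.934) and immediate early genes (0.477 to 0.654), and in the Crim1 split areal genes (0.497 to 0.980).

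Genes that turned sign are given as log2 differences. For P3 against P1, over all cells, these were Camk2d (-0.20), Klhl14 (0.0923), Ldb2 (0.0424), Tle4 (0.20) and Sox5 (0.0152). At a limit of 5% they were Klhl14 (0.24) and Crym (-0.11), with the highest doublet scores removed Crym (-0.00786), in excitatory neurons Tle4 (0.20) and without cluster 25 Gap43 (0.17). Without each sample Klhl14 ran from -1.07 to 0.42, Ldb2 from -0.45 to 0.0897, Crym from -0.23 to 0.53 and Gap43 from -0.65 to 0.0791. For CSN against SCPN, over all cells, they were Wls (0.19), Bcl11b (-0.15) and Tle4 (-0.36). Excitatory neurons turned Tle4 (-0.58), thinning Sox5 (0.0148) and a limit of 5% Lum (0.55). Without each sample Lum ran from -0.34 to 0.14, Ldb2 from -0.34 to 0.0593 and Sox5 from -0.17 to 0.17. In the Npy split, no filter turned Ldb2 (-0.00479), and Bcl11b ran from -0.16 to 0.00582 without each sample.

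In the Crim1 split, Tle4 turned with DESeq2 (-0.00880), without thinning (-0.00835), without the sample block (-0.0351), with called doublets kept (-0.14), with the highest doublet scores removed (-0.0285) and without cluster 25 (-0.00223). Klhl14 turned with the highest doublet scores removed (0.0968). At least 2 UMIs turned Bcl11b (0.0250) and Ldb2 (0.0462), no thinning Bcl11b (0.0123) and Gap43 (0.23), and the removal of cluster 25 Gap43 (0.0229). Without each sample Fezf2 ran from -0.0457 to 0.0256 and Tle4 from -0.0683 to 0.0917.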

Other observations

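The test of the separate runs, the gene choices and the alternatives below were chosen after the results were seen; the test of border macrophage markers was written before its result.

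Callosal-like cells of the same sorts differed in more genes between P1 and P3 than SCPN-like cells. Of 11923 genes, 3899 passed by edgeR's quasi-likelihood test with Benjamini-Hochberg, 1815 higher and 2084 lower at P3 (5254 at an unadjusted p under 0.05). The difference between the classes was not itself tested. Igfbpl1 fell by 2.19 ± 0.30 on the log2 scale and Sox11, a transcription factor gene of newborn neurons, by 2.13 ± 0.29 (SE, 2 samples per age; adjusted p = 0.000674 and 0.000616), both also in SCPN-like cells. Cluster 10, led by Igfbpl1 and Sox11, held most of the class at P1, 423 of 604 and 445 of 527 cells. Cluster 7, led by Cux2 and Rorb, held most at P3, 401 of 479 and 291 of 320 cells. The comparison is thus largely one of cluster 10 with cluster 7, and age cannot be told apart from it. Igfbpl1 and Sox11 are leading genes of cluster 10, so their fall is not independent of this. Npy stood at 244 and 68.7 CPM at P1 and at 430.04 and 269 CPM at P3 in these cells, a log2 change of 1.16 ± 0.45 that did not pass (adjusted p = 0.0695). After thinning, 12.8 and 4.44% of callosal-like cells had an Npy UMI at P1, 26.5 and 19.2% at P3 and 12.2% in CSN. The Npy change passed without P1 replicate 1 (2.36) and with no count filter (1.10), was 0.54 without P1 replicate 2 and 0.80 without P3 replicate 1, and its adjusted p ran from 6.00e-07 to 0.368 over the alternatives. The count was 3566 to 3663 without either P1 sample, 2418 without P3 replicate 1, 2189 without P3 replicate 2 and 2222 with DESeq2.

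Microglia-like cells of P3 replicate 2 carried an interferon-response signature. A list of 18 interferon and antigen-presentation genes, written after cluster genes were seen, stood at 5645 CPM there against 1114 and 1362 CPM at P1, 2643 CPM in P3 replicate 1 and 1545 CPM in CSN. Iigp1, an interferon-induced GTPase, was at 268 CPM against at most 4.30, Gbp2 at 244 against at most 20.6 and Cd74, the invariant chain of antigen presentation, at 264 against at most 40.1. Cluster 17, led by H2-Eb1, Cd74 and Iigp1, held 5.57% of the cells of this sample and at most 0.125% of any other. In SCPN-like cells the list stood at 135 CPM in this sample, within the range of 90.5 to 178 CPM of the others.

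The signature may be technical. A single aberrant run would leave at least 1 of the 3 runs of this sample among the others, but they stood at 5310.2, 5338 and 6206 CPM, the lowest 1.96 times the highest other run. Border macrophages mixed into the class could bring such genes, but their 6 markers stood at 143 CPM, 0.925 times the highest other sample. With 1 sample there is no replicate of the signature, and any cause shared by all of its runs stays open. No biological explanation was tested.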
